A study of Mus musculus with 4 samples.

How the data were processed

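Total RNA from the spleens of 4 mice of the 129Sv strain was hybridised to Affymetrix whole-transcript arrays, with 1 array per mouse. All 4 mice carried loxP-flanked alleles of RBP-J on both chromosomes. The 2 wild type mice had unmodified Ren1d, a renin gene of this strain, and the 2 leukaemic mice carried cre recombinase at both Ren1d alleles. Samples were grouped by their titles, and the replicate number came from the same label. The series' design text describes the replicates as individual mice, so the spread between arrays of a group includes the difference between animals.

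The authors deposited log2 expression values, 1 per probe set and array. RMA, which corrects background, equalises the intensity distributions of arrays and summarises the probes of a set, is named in the submitters' processing notes together with R 2.15.0 and limma 3.12.1. Their settings and order are not given in the sources used here. Detection calls and scan batches were not analysed here. Array medians were 8.03 and 8.02 in wild type and 7.96 in both leukaemic spleens. The number of arrays limits the precision.

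The value table held 23309 probe sets, and the platform annotation listed 21903 of them. A single gene symbol belonged to 20729 probe sets, several to 1174 and none to 1406. Names were taken only from the first class. Entrez identifiers of 20686 probe sets matched a mouse gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for symbols, for the chromosome of a gene and for the order of neighbouring genes. Genes with several probe sets (804 of 19297) were represented by the set with the highest mean over the 4 arrays, chosen after the fit and before adjustment.

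Leukaemic and wild type spleens were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no covariate, no filter on dim probe sets). P-values were adjusted by the Benjamini-Hochberg method over 19297 genes, and genes with an adjusted p under 0.05 were called. The fit had 2 residual degrees of freedom and an estimated 4.83 prior degrees of freedom. Standard errors (SE) are those of the moderated fit, and values are given as mean ± SD over 2 mice. No single gene can pass an exact permutation test in 2 against 2 mice, where the smallest two-sided p is 0.333.

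Before the data were examined, 27 gene lists were fixed for spleen cell types, B cell stages, proliferation, signalling and sex. They named 389 genes, of which 351 were measured here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with the correlation estimated from the data. That second test refers each list to the 2 residual degrees of freedom and has little power over 27 lists. Some genes stand in more than 1 list. Also fixed before the data were examined was the rule for the genes named in the text. It took Rbpj and Ren1, then the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between groups. Symbols that are only model numbers and antigen receptor segments were passed over. From each list it took up to 2 called members with the largest rise and up to 2 with the largest fall, or the 2 members of smallest p where none was called, and all sex-linked members. Ren1 was not analysed here, because no probe set carried it as its single symbol.

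The same scripts were tested on simulated data for all 19297 genes with the real replicate layout. They recovered 2%, 48%, 98% and 96% of genes changed by 0.5, 1, 2 and 3 on the log2 scale. Of 129 genes called there, 7 were unchanged ones and 0 had the wrong sign. The shifted list was found (1 of 1) and 0 others were called. Genes were drawn independently in that simulation, while list correlations estimated in the real data reached 0.97 (neutrophil). It therefore does not test false list calls among correlated genes. A chromosome raised by 0.25 (log2) in leukaemic replicate 1 was found in a further simulation (1 of 1), with 0 others called. Chromosome labels were shuffled first, which removes any real shift of the other chromosomes. The 0 therefore does not test how specific such calls are in the real data.

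Alternatives covered centring, quantile normalization, a filter on dim probe sets, the variance prior, a minimum fold change, the choice of probe set, all rows in the fit, the replicate number as a block, an estimated correlation for the lists and each mouse left out in turn. An adjustment of p-values without exocrine pancreas genes, with the fit itself unchanged, was added after the data were seen. Chromosome and tissue checks used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Group was fully confounded with cre at Ren1d, age and spleen weight. Sex was not a covariate. With 1 male, a term for sex would take that mouse out of the group contrast, as in the fit without leukaemic replicate 2.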

Results

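Expression of 19297 genes was measured in the spleens of 2 wild type mice and of 2 mice with B cell leukaemia. The leukaemic mice carried cre at the renin locus Ren1d together with floxed RBP-J, the gene of the DNA-binding protein through which Notch receptors act. Wild type mice were 80 and 81 days old, with spleens of 0.12 g and 0.16 g. Leukaemic replicates 1 and 2 were 107 and 93 days old, with spleens of 0.7 g and 0.47 g. All mice were female except leukaemic replicate 2. The comparison asks how gene expression of the leukaemic spleen differs from that of a spleen without the disease.

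Rbpj, the floxed gene, had values of 9.99 and 9.74 in wild type and 9.78 and 9.18 in leukaemic replicates 1 and 2 (log2, probe set 10521913). The difference of -0.38 (SE 0.22, limma adjusted p = 0.41) did not exceed the replicate spread. A second probe set, 10521911, read 6.40 and 6.71 in wild type and 6.58 and 6.49 in leukaemic spleen. Whether either probe set lies in the floxed part is not given in the sources used here, so these values do not check the genotype. Ren1 was not analysed here.

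Genes of the surrogate light chain and of receptor gene recombination were among the largest rises in leukaemic spleen. Igll1, a surrogate light chain component of the precursor B cell receptor, rose from 7.46 ± 0.03 to 12.93 ± 0.12 (SD, n = 2), a log2 fold change of 5.47 (SE 0.14, limma adjusted p = 5.8e-05). Its partner Vpreb1 rose from 6.51 ± 0.05 to 9.87 ± 0.08 (SD, n = 2). Rag1 and Rag2, which encode the recombinase that assembles antigen receptor genes, rose from 6.40 ± 0.26 to 9.97 ± 0.25 and from 5.15 ± 0.04 to 8.46 ± 0.25 (SD, n = 2). The largest fall was that of Adamdec1, a metalloprotease-like gene, from 9.89 ± 0.31 to 6.27 ± 0.02 (SD, n = 2), a log2 fold change of -3.62 (SE 0.18, limma adjusted p = 0.00067). In all, 276 genes rose and 199 fell, 185 and 121 of them at least 2-fold. The wild type means of the 10 largest rises all lay under 8.04, the highest wild type mean among 29 liver and pancreatic islet genes (median 6.41), a comparison chosen after the data were seen, as did the leukaemic means of 7 of the 10 largest falls. These low levels are not shown to be above background, so the differences given for those genes are not exact folds.

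The other large rises included Enpep, the aminopeptidase also known as the B cell antigen BP-1 (log2 fold change 4.77, SE 0.23), and Raet1d, a ligand of the activating receptor NKG2D (4.49, SE 0.47). Crhbp, which binds corticotropin-releasing hormone, rose by 4.35 (SE 0.37), and Hmgcll1 by 4.06 (SE 0.24). Gfra1, a receptor for glial cell line-derived neurotrophic factor, rose by 3.47 (SE 0.17), and Lgr5, an R-spondin receptor, by 3.37 (SE 0.22). The natural killer (NK) cell receptor genes Ncr1 and Klrd1 had log2 fold changes of -2.29 (SE 0.24) and -2.05 (SE 0.31). Klra17, a Ly49 family receptor gene that is not in the NK cell list, was at -2.71 (SE 0.29). Cd7 and Cd96, both found on T and NK cells, were 5.33-fold (SE 0.41 on the log2 scale) and 3.99-fold (SE 0.36) lower. Siglech, a marker of plasmacytoid dendritic cells, was at -2.15 (SE 0.26), and the chemokine receptor gene Ccr9 at -2.02 (SE 0.15). Fcmr, an IgM receptor of lymphocytes, was at -2.01 (SE 0.24), and Map3k19 at -2.34 (SE 0.16). Adjusted p for these genes lay between 0.00067 and 0.047. Without leukaemic replicate 1 and without leukaemic replicate 2, the log2 fold change was 3.65 and 5.33 for Raet1d, 3.74 and 4.95 for Crhbp, and -1.73 and -3.10 for Cd7.

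**Figure D1:**
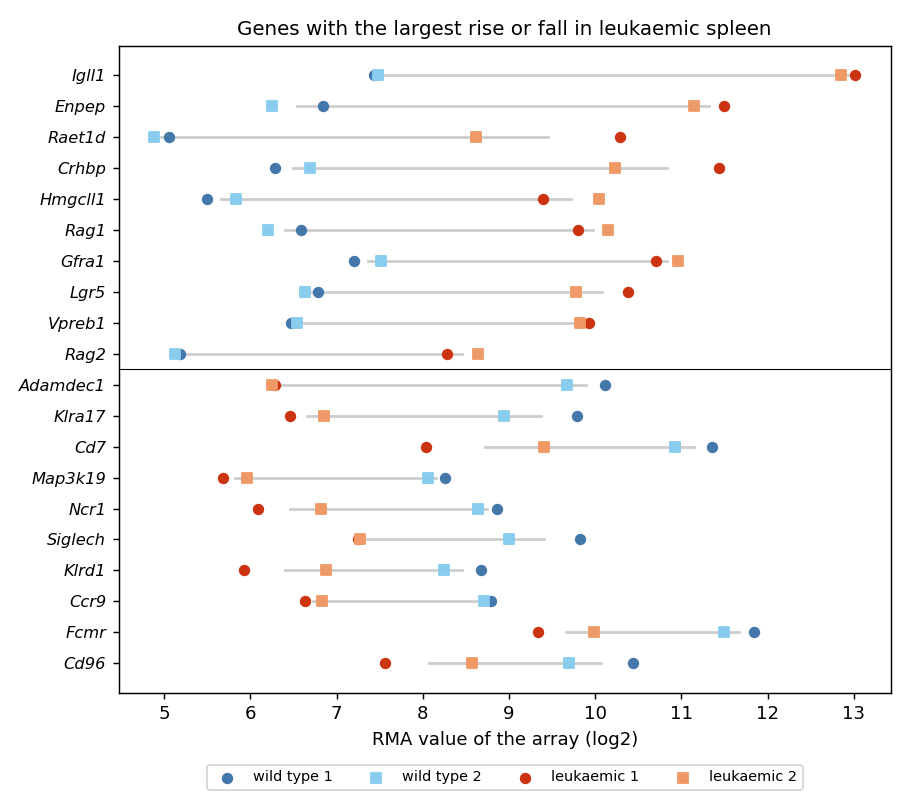
RMA values (log2, horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall, 1 point per array, with grey lines joining the group means. In each of these genes both leukaemic arrays lie on the same side of both wild type arrays; the arrays of Igll1 span 7.44 to 13.02.

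Counts of changed genes moved with each mouse left out, in fits that also fall from 2 residual degrees of freedom to 1. The estimated prior degrees of freedom were 2.79 without a wild type mouse and infinite without a leukaemic one, against 4.83, so these counts are not directly comparable. Without wild type replicate 2, limma called 0 genes higher and 0 lower, with 3142 at an unadjusted p under 0.05, against 3989 with all arrays. Without wild type replicate 1 it called 12 and 26, without leukaemic replicate 1 282 and 209, and without leukaemic replicate 2, the male, 450 and 593. Of the 475 calls from all arrays, 0 had the opposite sign in any of these fits. That was fixed in advance, as the arrays of all 475 do not overlap between groups. Of the 46 called genes named here, 0, 6, 35 and 41 were called in these fits. Centring each array on its median gave 343 higher and 155 lower (68.9% higher, against 58.1% as deposited). Wild type replicate 2 also held transcripts of exocrine pancreas. Of 35 measured acinar genes, 29 lay at least 1 (log2) above all 3 other arrays there, among them Cpa1 at 12.86 against 6.74 to 6.79. None of the 35 was called, and leaving them out of the adjustment, with the same fit, gave 276 higher and 200 lower. So few uncalled genes can hardly move the adjustment, so these counts do not test what pancreas RNA does to other genes.

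Across the list of precursor B cell genes, 13 of 21 measured members rose, 1 fell and 7 did not pass; adjusted over the list alone, 16 rose and 1 fell. The list stood above other genes (camera adjusted p = 1.7e-17), with adjusted p = 0.28 with an estimated correlation. Flt3, a cytokine receptor of early progenitors, was the member that fell (log2 fold change -1.33, SE 0.19). Both leukaemic mice had similar list means, 1.61 and 1.70 above wild type. Members of the list for B cells in general went both ways. Ebf1 and Pou2af1, transcriptional regulators of B cells, rose by 1.11 (SE 0.18) and 0.92 (SE 0.14), and the receptor genes Cd180 and Cd22 had log2 fold changes of -0.91 and -0.84 (SE 0.14 each). The other 13 of 17 did not pass, 2 rose and 7 fell adjusted over the list alone, and the list was not called (adjusted p = 0.085). It was called lower without wild type replicate 2 (adjusted p = 0.0097) or without leukaemic replicate 2 (0.012), and after quantile normalization (0.031).

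Lists of later B cell stages were lower. Of 14 mature B cell genes 3 fell, and all 14 fell adjusted over the list alone (camera adjusted p = 1.5e-10; adjusted p = 0.34 with an estimated correlation). Cr2, the complement receptor CD21, had a log2 fold change of -1.86 (SE 0.24), and Ltb, which encodes lymphotoxin beta, -1.72 (SE 0.22). Among 10 marginal zone B cell genes 3 fell, and 5 adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.34 with an estimated correlation). Dtx1, a Notch target, was at -1.95 (SE 0.26), beside Cr2. Cd5 fell to 8.84 ± 0.32 from 10.25 ± 0.23 (SD, n = 2) and was the 1 of 9 genes of the B1 cell list to pass; adjusted over the list alone 4 fell. Cd5 is also expressed by T cells, whose list mean was -1.15. The B1 cell list was called lower (camera adjusted p = 0.024, and 0.41 with an estimated correlation), with a mean of -0.43. Its call was lost without wild type replicate 1 (mean -0.41) or leukaemic replicate 1 (mean -0.17). Of 7 germinal centre genes 0 passed, and 1 rose and 5 fell adjusted over the list alone; Bcl6 had a difference of -0.80 (SE 0.19) and Mybl1 of 0.79 (SE 0.20). The list was called lower (camera adjusted p = 0.034; adjusted p = 0.41 with an estimated correlation), but not without wild type replicate 1 (0.41), leukaemic replicate 1 (0.28) or the dimmest 33.3% of genes (0.05002).

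In the plasma cell list 1 of 11 genes passed, also adjusted over the list alone. That gene, Irf4, a transcription factor that also acts in precursor B cells, rose by 1.02 (SE 0.16). The list was not called (adjusted p = 0.16); its mean was -0.53 in leukaemic replicate 1 and 0.07 in leukaemic replicate 2, and without leukaemic replicate 2 it was called lower (adjusted p = 0.00060). MHC class II genes fell in 3 of 8 cases and in 8 adjusted over the list alone (camera adjusted p = 4.9e-08; adjusted p = 0.34 with an estimated correlation). Ciita, the master regulator of these genes, had a log2 fold change of -1.53 (SE 0.28), and H2-DMa, which serves peptide loading, -1.45 (SE 0.19).

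Marker genes of other leukocytes were lower. Among T cell genes 7 of 19 fell, and 17 adjusted over the list alone (camera adjusted p = 2.6e-12; adjusted p = 0.34 with an estimated correlation). Cd3g and Cd3e, chains of the T cell receptor complex, had log2 fold changes of -1.78 (SE 0.33) and -1.70 (SE 0.29). Of 13 NK cell genes 7 fell, and 11 adjusted over the list alone (camera adjusted p = 4.5e-08; adjusted p = 0.34 with an estimated correlation), led by Ncr1 and Klrd1. Dendritic cell genes fell in 5 of 12 cases, and in 9 adjusted over the list alone (camera adjusted p = 1.8e-08; adjusted p = 0.34 with an estimated correlation), led by Siglech and Ccr9. Neutrophil genes fell in 3 of 15 cases, and in 13 adjusted over the list alone (camera adjusted p = 5.5e-10; adjusted p = 0.36 with an estimated correlation). Camp, an antimicrobial peptide of neutrophil granules, was at -1.24 (SE 0.21), and Csf3r, the receptor of granulocyte colony-stimulating factor, at -1.22 (SE 0.19). In leukaemic replicates 1 and 2 the list means were -1.42 and -0.88 for T cells, -1.38 and -0.90 for NK cells, -1.55 and -0.64 for neutrophils, and -1.07 and -1.06 for dendritic cells.

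Macrophage genes did not pass singly (0 of 17), though 11 fell adjusted over the list alone and the list was lower (camera adjusted p = 3.5e-07; adjusted p = 0.34 with an estimated correlation). Slc40a1, the iron exporter ferroportin, differed by -0.76 (SE 0.15), and Siglec1, a surface lectin of metallophilic macrophages, by -0.95 (SE 0.20). Of 14 erythroid genes 0 passed, also adjusted over the list alone; Fech and Alas2, enzymes of haem synthesis, differed by -0.62 (SE 0.19) and -0.54 (SE 0.18). The erythroid list was lower (camera adjusted p = 0.00026; adjusted p = 0.41 with an estimated correlation), while its mean differed by 0.52 between the wild type mice, higher in replicate 2. Gp9, a platelet glycoprotein, was the 1 of 9 megakaryocyte genes to fall (log2 fold change -0.75, SE 0.14), and all 9 fell adjusted over the list alone (camera adjusted p = 8.6e-08; adjusted p = 0.34 with an estimated correlation). Of 11 stem and progenitor genes 1 fell, Flt3, also adjusted over the list alone; that list was not called (adjusted p = 0.065), except without wild type replicate 2 (0.036). Stroma and endothelium had 1 of 16 genes lower, and 3 adjusted over the list alone. That gene, Ccl19, a chemokine of the T cell zone, had a log2 fold change of -1.19 (SE 0.22), and the list was lower (camera adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation), but not without wild type replicate 1 (0.33).

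**Figure D2:**
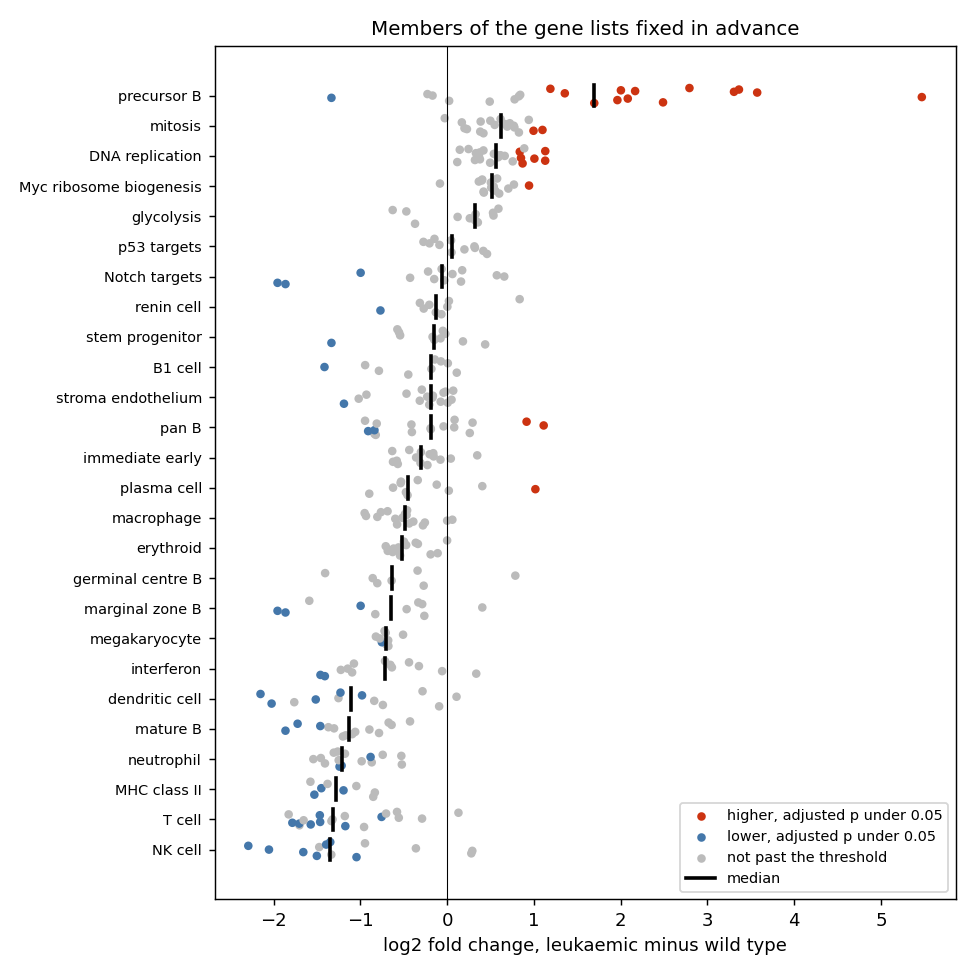
Log2 fold change (leukaemic minus wild type, horizontal axis) of every measured member of 26 gene lists, 1 point per gene, coloured by call, with black bars at the list medians. The precursor B cell median lies at 1.70 and the NK cell median at -1.35.

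Genes of DNA replication and mitosis were higher. Of 23 replication genes 6 rose, and 15 adjusted over the list alone (camera adjusted p = 2.1e-13; adjusted p = 0.34 with an estimated correlation). Prim1, a primase subunit, and Chaf1b, a chromatin assembly factor, each rose by 1.13 (SE 0.15 and 0.17). Of 19 mitosis genes 2 rose, the spindle checkpoint kinases Bub1b (2.14-fold, SE 0.17 on the log2 scale) and Bub1 (1.99-fold, SE 0.15), and 10 adjusted over the list alone (camera adjusted p = 3.2e-09; adjusted p = 0.36 with an estimated correlation). Wild type replicate 2 stood 0.40 above replicate 1 in the mitosis mean. Nop58, a nucleolar protein, rose by 0.94 (SE 0.17) as 1 of 16 genes of Myc-linked ribosome biogenesis; 15 rose adjusted over the list alone (camera adjusted p = 3.2e-09; adjusted p = 0.34 with an estimated correlation). In glycolysis 0 of 12 genes passed, and 2 rose and 1 fell adjusted over the list alone. Tpi1 differed by 0.59 (SE 0.15) and the glucose transporter gene Slc2a1 by -0.63 (SE 0.16). The glycolysis call (camera adjusted p = 0.047; adjusted p = 0.38 with an estimated correlation) ended with median centring (0.057), quantile normalization (0.090), the dimmest 33.3% of genes left out (0.11), or without wild type replicate 2 (0.16) or leukaemic replicate 1 (0.25) or 2 (0.19).

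Notch target and receptor genes included 3 of 13 that fell, also 3 adjusted over the list alone. These were Dtx1, Cr2 and, outside the naming rule and chosen after its value was seen, the receptor gene Notch2 (adjusted p = 0.037). All 3 also belong to the marginal zone list. The Notch list was not called (adjusted p = 0.065), but was called lower after median centring (0.045) and without leukaemic replicate 2 (0.0012). Of 9 genes of renin-producing cells and their signalling, Agtr1a, an angiotensin receptor gene, fell from 10.34 ± 0.12 to 9.57 ± 0.03 (SD, n = 2); 1 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.27). Interferon-response genes fell in 2 of 13 cases, the chemokine genes Cxcl9 (-1.46, SE 0.23) and Cxcl10 (-1.41, SE 0.15), and in 7 adjusted over the list alone (camera adjusted p = 1.4e-05; adjusted p = 0.34 with an estimated correlation). The interferon mean was also lower in wild type replicate 2 than in replicate 1, by 0.52. Of 15 immediate early genes 0 passed and 4 fell adjusted over the list alone; Nr4a1 differed by -0.63 (SE 0.14) and Egr2 by -0.62 (SE 0.16). Their list was lower (camera adjusted p = 0.0020; adjusted p = 0.34 with an estimated correlation), but not without leukaemic replicate 1 (0.10). In the p53 target list 0 of 11 genes passed, also adjusted over the list alone. Aen differed by 0.46 (SE 0.14) and Ccng1 by 0.42 (SE 0.17), and the list was not called (adjusted p = 0.23).

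The 4 sex-linked genes followed the sex in the labels. Xist, which is expressed from the inactive X chromosome, was at 12.39, 12.49 and 12.56 in the females and at 6.45 in the male leukaemic replicate 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 10.07, 8.91 and 8.80 in that mouse and at no more than 4.09, 5.65 and 4.93 in the others. None of the 4 passed the test, also adjusted over the list alone, and the list was not called (adjusted p = 0.24) except without leukaemic replicate 1 or with the replicate number as a block (0.019).

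**Figure D3:**
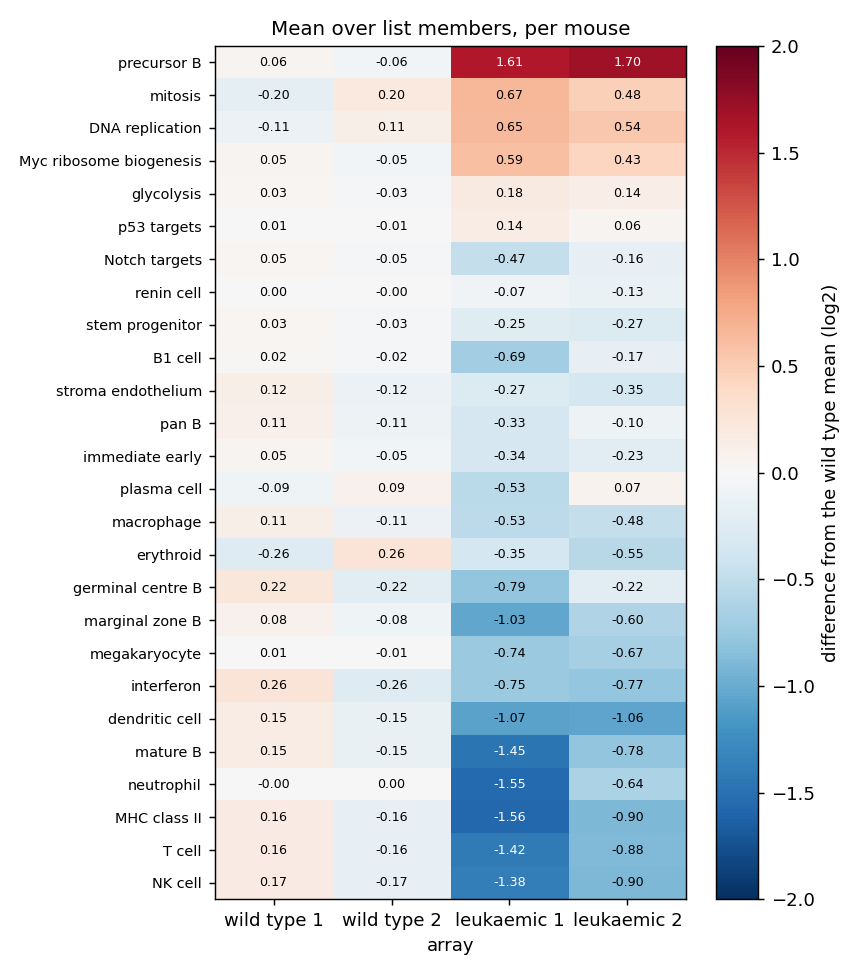
Mean over the measured members of each gene list in each mouse, as the difference from the wild type mean (log2, colour scale and printed values). Precursor B cell genes are at 1.61 and 1.70 in the leukaemic mice, and neutrophil genes at -1.55 and -0.64.

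In total, camera called 5 lists higher and 15 lower at the preset correlation, and 0 with an estimated correlation. The smallest camera p with an estimated correlation was 0.010, for precursor B cell genes (adjusted p = 0.28). That test has 2 residual degrees of freedom and little power, so its 0 decides neither for nor against the calls. The preset calls assume a correlation of 0.01, while estimates reached 0.97 (neutrophil). Cre at Ren1d, age and spleen weight differed fully between the groups, so their part in these differences was not separated from that of the leukaemia.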

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

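Some probe sets carried signal outside the comparisons, because the platform table pairs them with several gene symbols or with none. There were 2580 of them, and 34 passed the threshold when limma was fitted to all probe sets, 18 higher and 16 lower in leukaemic spleen. That is 1.32% of them, against 1.72% of the probe sets with 1 symbol. Their genes were not named here.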

How the results depend on the processing

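Of the alternatives, only leaving pancreas genes out of the adjustment was chosen after the data were seen. Together they changed the sign of 0 of the 475 called genes. With a mouse left out this was fixed in advance, as the arrays of all 475 do not overlap between groups. Several other settings, such as the robust prior and the minimum fold change, leave the fold changes as they were. Genes called higher and lower numbered 157 and 89 with quantile normalization, 501 and 473 with a robust prior, and 44 and 6 against a 1.5-fold minimum, which asks for a larger change. Other settings with all 4 arrays, apart from the replicate block, stayed within 1.5 times of 276 and 199. With each mouse left out, counts ranged from 0 to 450 higher and 0 to 593 lower. Those fits keep 1 mouse in an arm, assume that it varies like the others and have 1 residual degree of freedom. Without a leukaemic mouse the estimated prior degrees of freedom were infinite, which gives every gene 1 common variance, so those counts are not comparable with the others. With the replicate number as a block the counts were 785 and 908, which held all 475 calls. That fit had 1 residual and an estimated 19.7 prior degrees of freedom, against 4.83 prior in the main fit. Genes at an unadjusted limma p under 0.05 numbered 3837 there, against 3989. The larger counts therefore do not show that pairing removed variance. Whether equal numbers pair the mice is not given in the sources used here. Same-numbered deviations correlated at -0.089 over genes. With 2 pairs, and genes that are not independent replicates, that value does not decide it. Pancreas transcripts in wild type replicate 2 and the sex of leukaemic replicate 2 also enter these deviations. The block also called the Notch and sex-linked lists and lost glycolysis. With an estimated correlation 0 lists were called higher and 0 lower, against 5 and 15. The estimate was far above the preset 0.01 in some lists, such as neutrophil (0.97). For precursor B cell and megakaryocyte genes it was below, at -0.00496 and -0.028. Their unadjusted camera p still rose, from 6.3e-19 to 0.010 and from 3.5e-08 to 0.029. These values argue against a higher correlation as the cause in those 2 lists. With an estimated correlation, camera also tests each list on the 2 residual degrees of freedom, which raises p whatever the correlation. How much each part adds in the other lists was not tested. Lists kept their direction with each mouse left out, except that the plasma cell mean ranged from -0.53 to 0.0745. Differences of the sex-linked genes ranged from -0.13 to 3.30 for Kdm5d, -0.056 to 3.93 for Uty and -5.99 to 0.12 for Xist, crossing 0 without the male. Rbpj stayed negative and not called in every alternative. Signal over background was not analysed here and limits what can be said of dim genes.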

Other observations

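Several called genes outside the naming rule were picked after their values were seen. H60b, another NKG2D ligand gene, rose by 2.82 on the log2 scale (limma adjusted p = 0.048) beside Raet1d, while Klrk1, which encodes NKG2D, differed by -1.47 and was not called (adjusted p = 0.058). Enzymes of lipid synthesis that rose were Elovl6 (2.24, adjusted p = 0.0014), Gpat3 (2.37, adjusted p = 0.0020) and Gpam (2.16, adjusted p = 0.0023), and the metabolic coactivator gene Ppargc1a rose by 2.12 (adjusted p = 0.0023). The chemokine receptor genes Cxcr6 and Cxcr3 had log2 fold changes of -1.52 (adjusted p = 0.036) and -1.37 (adjusted p = 0.029). Lipid synthesis, NKG2D ligands and chemokine receptors were not tested as groups, and 0 genes were called without wild type replicate 2.

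Leukaemic mice also differed from each other. At least 2 (log2) above all 3 other arrays, a limit chosen after the data were seen, stood 10 genes in leukaemic replicate 1 and 10 in replicate 2. In replicate 2, the male, 3 of the 10 were the Y-linked Eif2s3y, Uty and Kdm5d. Vsig4, a complement receptor of macrophages, was at 10.13 in leukaemic replicate 1, 2.63 above the next array. Radx was at 9.63 there and at 5.60 to 6.05 elsewhere. Fcrl6 was at 11.04 in leukaemic replicate 2 and at 6.24 to 6.97 elsewhere, where Fetub stood 3.69 above the next array. With 1 mouse each these are values without a test. Klk1b22 was high in 1 mouse of each group, at 10.35 in wild type replicate 1 and 10.29 in leukaemic replicate 2, and at 7.09 and 6.25 in the others.

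Of the tests that follow, those on pancreas genes, on the correlation of arrays, on unequal falls of cell lists, on random placing and on the baseline of the chromosome shifts were chosen after the result was seen, as were the limit to bright genes, the 3 chromosomes and the windows around other genes.

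Pancreatic enzyme genes were high in wild type replicate 2: 82.86% of acinar genes (29 of 35) lay at least 1 (log2) above the other arrays, 18 of them at least 4. Liver genes (0.0%, 0 of 16) and islet genes (0 of 14) did not, which argues against liver RNA. The correlation with wild type replicate 1, 0.986126 over genes, exceeded every correlation between a wild type and a leukaemic array (0.966 to 0.980), which argues against a whole sample of another tissue. Exocrine pancreas RNA in that library is a candidate source, since the pancreas lies beside the spleen. No biological explanation was tested.

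Lists of other cell types fell by unequal amounts. Among members above the median signal, the median log2 fold changes of T cell, NK cell, dendritic cell and neutrophil genes were -1.32, -1.39, -1.24 and -1.22 over both leukaemic mice (-1.58, -1.66, -1.35 and -1.53 in replicate 1, -0.92, -1.13, -1.06 and -0.67 in replicate 2). Those of megakaryocyte, erythroid, macrophage and stroma genes were -0.71, -0.52, -0.49 and -0.21 (-0.72, -0.36, -0.49 and -0.27 in replicate 1, -0.70, -0.59, -0.51 and -0.27 in replicate 2). In replicate 2 neutrophil genes thus fell no more than megakaryocyte genes. Stroma minus T cell, a pair picked as far apart, was 1.31 and 0.64316 in the leukaemic mice. In wild type it was -0.09 and 0.09. These medians argue against 1 common dilution by leukaemic cells as the whole cause for that pair of lists. Stroma members were unlike each other, with quartiles of -0.47 and -0.02 and Ccl19 at -1.19. Their median therefore does not hold for each gene. A permutation of genes gave p = 0.0004 but treats genes as independent and does not cover the spread between mice. A lower level of the stroma genes on the array is argued against, as their median wild type level was 0.17651 above that of the T cell genes. Levels of different probe sets do not show how strongly each responds, so a weaker response is not decided by this value. Unequal changes in the numbers of cell types in the leukaemic spleen, or altered expression within them, may remain as a hypothesis. RMA equalises the arrays, so the values do not give amounts per spleen. Leukaemic spleens weighed 0.7 g and 0.47 g, against 0.12 g and 0.16 g in wild type. The falls are therefore not shown to be a loss of cells. The hypothesis is confounded with cre at Ren1d, age and spleen weight and would need counts of each cell type to test.

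Bright genes of 3 chromosomes were raised in 1 leukaemic mouse each: chromosomes 10 (0.2031, 496 genes) and 12 (0.2353, 331 genes) in replicate 1 and chromosome 11 (0.1791, 835 genes) in replicate 2, as medians on the log2 scale against wild type. The other 37 shifts lay between -0.0977 and 0.0802, and without the limit to bright genes the 3 were 0.0717, 0.0956 and 0.0544. Random placing gave adjusted p = 0.001 for each (unadjusted 0.0001, the smallest that 10000 draws can give), though 11 of the other shifts also had an adjusted p under 0.05, so the 3 stand apart by size and not by p. A single wild type array as the cause is argued against, as each of the 3 shifts was at least 0.1777 against either wild type array alone. Split into 4 parts of neighbouring genes, each of the 3 was raised in every part (lowest 0.1184, against at most 0.0497 for the lowest part of any other), so a gain of whole chromosomes in part of the cells may be a hypothesis, which would need DNA to test.

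A flanking haplotype carried with the cre allele may also change genes around Ren1. Of the 100 measured genes nearest to it in gene order 6.0% were called, against 2.443% of the others (Fisher's exact test, one-sided p = 0.0371). As many calls stood in 6.903% of 17267 windows of 100 genes, so the test does not decide.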
